A study of Nicotiana tabacum with 6 samples.

How the data were processed

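RNA was sequenced from leaves of 6 tobacco samples, 3 of the isoprene-emitting line (IE) and 3 of the azygous non-emitting control (NE), all at 7 weeks after seeding. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a stranded mRNA kit. The submitters' processing notes name Trimmomatic 0.32, FastQC, featureCounts and limma, with no role or order, and TAIR10 as a genome build. TAIR10 is an Arabidopsis build, while the gene models and scaffolds in the deposited annotation are those of the tobacco TN90 assembly. The aligner is not given in the sources used here, nor whether counting used the strand, so reads of overlapping genes and of near-identical copies from the 2 subgenomes of tobacco could have been split or shared between gene models. Scaffold names are as the deposited files give them.

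The authors deposited 1 table with 44639 rows, which repeat a gene once for each annotated transcript match, and 14048 distinct genes out of 88208 gene models. Its expression columns are in RPKM, computed by the authors with the gene's full span as length, introns included: the stated length equals end minus start plus 1 in all 14048 genes (median 6158.5 bp), so RPKM values understate genes with long introns and levels should be compared between lines and not between genes. RPKM times length gives whole reads per library total for 100% of values in each library, within a tolerance of 0.05 reads. The lowest value over genes of the third highest CPM was 10.0, so the table holds genes with at least 10 CPM in at least 3 libraries. A gene silent in 1 line can pass this filter, but a gene that is low in both lines was not analysed here. The deposited average log expression equals the mean of voom's log2 CPM with 0.5 added to the reads, which fixes the library totals the authors used. Of these totals, 68.6% to 75.6% of reads lie in the listed genes. The deposited table also gives log2 fold changes, p-values and adjusted p-values of the authors, coded as NE minus IE, and these were turned to IE minus NE. The moderated t and log-odds in the same table are scores of the authors' limma fit, per the file headers, and were not used. Gene descriptions were taken from the Arabidopsis and tomato matches in the deposited files, with an e-value of at most 1e-05: 13324 genes had an Arabidopsis match, 13651 a tomato match and 13740 either.

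The expression columns are numbered 1 to 3 in each line, whereas the sample titles carry other replicate numbers, so each column was assigned to its line and not to a sample, and the numbers only name the libraries. With unit and file unknown beforehand, a test for counts had been chosen for a count table and limma for normalized values. As the values are RPKM, limma was used. Of the methods meant for counts, only voom was run, on reads recovered from the RPKM values.

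The comparison used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with the line as the only term, for the 13152 genes with an RPKM of at least 1 in at least 3 of the 6 libraries. P-values were two-sided and adjusted by Benjamini-Hochberg over these genes, with a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale and understate the change of low genes. A change of at least 2-fold means an absolute log2 fold change of at least 1. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 45 lists with at least 5 tested members, and again with an estimated correlation and with fry, which asks whether the genes of a list move on balance in 1 direction. The lists, their member rules, the tests and the rule for named genes were fixed before the data were examined. That rule took the 10 genes of each direction with the smallest p among changed genes with at least a 2-fold change, separated libraries and an informative description, up to 4 changed members of each list past the set test (or with at least 5 changed genes) for at most 8 lists in order of camera p, and the 3 most expressed genes of the MEP pathway. Genes outside it were named where a count of 5 or fewer members was given, after their values were seen. Of the cell wall list, single members are given only in part, and the changed members of the P450, auxin and calcium lists are not listed singly.

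The test was tried on simulated data, with reads drawn from the real means and library totals and with 200 genes changed by known folds. Each gene had the same dispersion in both lines, the mean of its within-line values (median 0.0239), and genes were drawn independently. For IE against NE, with 13105 simulated genes tested, limma called 44% of genes raised 2-fold, 88% of those raised 4-fold, 22.4% of those lowered to 0.5 and 87.8% of those lowered to 0.25 of their level, and 8 of 12907 unchanged genes, 6.25% of all calls. So in this simulation changes of about 2-fold were often missed with 3 libraries per line. The real IE libraries differed more among themselves than the NE libraries, so recovery and false calls in the real data may differ from these values.

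Reads recovered from the RPKM values were used for gene levels near 0. A gene was called near-absent in a library when its CPM was under 2% of the NE mean (for an NE library, of the mean of the other NE libraries). The partner gene model of a gene was the only other listed gene with the same tomato match. Pairs whose partner was itself near-absent in an IE library were left out, so partners near 0 were excluded beforehand. A shared match was taken to mark the other subgenome's copy, which was not checked. Medians over genes have 95% bootstrap intervals from 10000 resamples, ratios over 1 or more reads have exact Poisson intervals, and a floor of 3 reads over the group was used where IE had none. The bootstrap resampled genes or pairs, so its intervals measure the spread between genes and not between libraries. Neighbouring genes were treated as independent. The clustering of near-absent genes on scaffolds was tested with 10000 random draws of as many listed genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps. Alternatives set beforehand were a pseudocount of 0.1, no filter on low values, an estimated correlation between genes and leaving out each library in turn. Those added after the data were seen were voom on the recovered reads, sample quality weights, libraries scaled to the same total of listed genes, quantile normalization, and leaving out the near-absent genes or the genes that match tomato chromosome 1.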

Results

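Leaf transcripts were compared between 2 lines of tobacco (Nicotiana tabacum, cultivar Samsun) at 7 weeks after seeding. The isoprene-emitting line (IE) carries the isoprene synthase (ISPS) of white poplar, the enzyme that turns dimethylallyl diphosphate into the volatile isoprene. The non-emitting line (NE) is the azygous control, which lacks the transgene. Each line had 3 libraries, and the plants were grown without stress in a greenhouse. The deposited table lists 14048 genes as RPKM (reads scaled by the length of the gene's span and by the library's total). Between 20916573 and 23736460 reads per library fell in these genes, and 1 read corresponded to between 0.0302 and 0.0355 CPM (reads scaled by the library total alone). The labels do not say whether the libraries of a line came from separate plants, so the p-values measure only the spread between these libraries. The series' design text gives NE as the name of both lines, so the lines were told apart by the emission phenotype in the sample labels, and the direction of each fold change rests on these labels. The transgene itself was not analysed here.

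The single comparison asks which leaf transcripts differ between the isoprene-emitting and the azygous line. With 1 line of each kind, an effect of isoprene cannot be told apart from other differences between the lines. The genes missing from IE libraries, described below, are such a difference. Transcripts that were higher in IE included those of 3 of 12 terpene synthases, a hydroxymethylglutaryl-CoA reductase, 3 of 35 WRKY factors, 3 of 38 class III peroxidases and 3 xyloglucan endotransglucosylases. No gene list passed its test with a correlation between genes that was estimated from the data (lowest adjusted p 0.56). Transcripts that were lower in IE included an ent-kaurene synthase, 2 D-type cyclins, 2 pectate lyases, and 15 genes on 5 scaffolds whose reads were almost missing from all 3 IE libraries. Of 13152 genes tested with limma on log2(RPKM + 1), 266 changed at an adjusted p under 0.05, 183 of them higher and 83 lower in IE. A change of at least 2-fold was found for 173 genes, 130 higher and 43 lower. In all 266 the 3 libraries of one line lay above the 3 of the other. Such separation was seen in 3609 of the tested genes, or 27.4%, against 10% by chance for 3 against 3. The number of changed genes moved with single libraries. It was 67 without IE library 1 (36 higher and 31 lower), 1095 without IE library 2 (765 and 330), 465 without IE library 3 (291 and 174), and 48 (24 and 24), 29 (7 and 22) and 31 (14 and 17) without NE library 1, 2 and 3. At 2-fold or more the 130 higher and 43 lower became 7 and 22 without NE library 2. The 15 genes almost missing from IE were among the lower calls in every removal. Counted without them, 183 were higher and 68 lower with all libraries, 24 and 9 without NE library 1, 7 and 7 without NE library 2, 14 and 2 without NE library 3, and 36 and 16 without IE library 1. All 266 genes kept their direction in each of the 6 removals and 22 also kept their call.

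The genes with the smallest p among those higher in IE spanned several functions. The xyloglucan endotransglucosylase gene_28423, a cell wall enzyme that cuts and rejoins xyloglucan chains, was at 133 ± 9.62 RPKM in IE and 28.8 ± 4.87 in NE (SD, n = 3 each), with a log2 fold change of 2.18 ± 0.15 (SE) and an adjusted p of 0.00174. The beta-glucanase gene_75491 rose from 27.1 ± 5.84 RPKM in NE to 323 ± 131 in IE (SD, n = 3 each), the highest of these 10 genes in IE. A carotenoid cleavage dioxygenase 1 (gene_76650), an enzyme family that makes volatile apocarotenoids, rose from 1.57 ± 0.141 to 5.59 ± 0.347 RPKM (SD, n = 3 each). The RING/U-box protein gene_66715, whose tomato match is annotated as a receptor-like kinase, rose by 2.12 ± 0.14 on the log2 scale (SE), and the heavy-metal-associated domain gene gene_17873 by 2.08 ± 0.17. These 5 genes were called in all 6 removals of a library. The other 5 were a CBL-interacting protein kinase (gene_40898), a plant cadmium resistance 2 homologue (gene_7290), a DNA binding protein-like gene (gene_38270), a multiprotein bridging factor 1 (gene_66500) and an aldehyde dehydrogenase (gene_11315). Their log2 fold changes were 1.89, 1.72, 1.51, 1.36 and 1.21, and each missed the threshold in at least 1 removal, with an adjusted p of at most 0.0625 (gene_11315, without NE library 2).

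**Figure D1:**
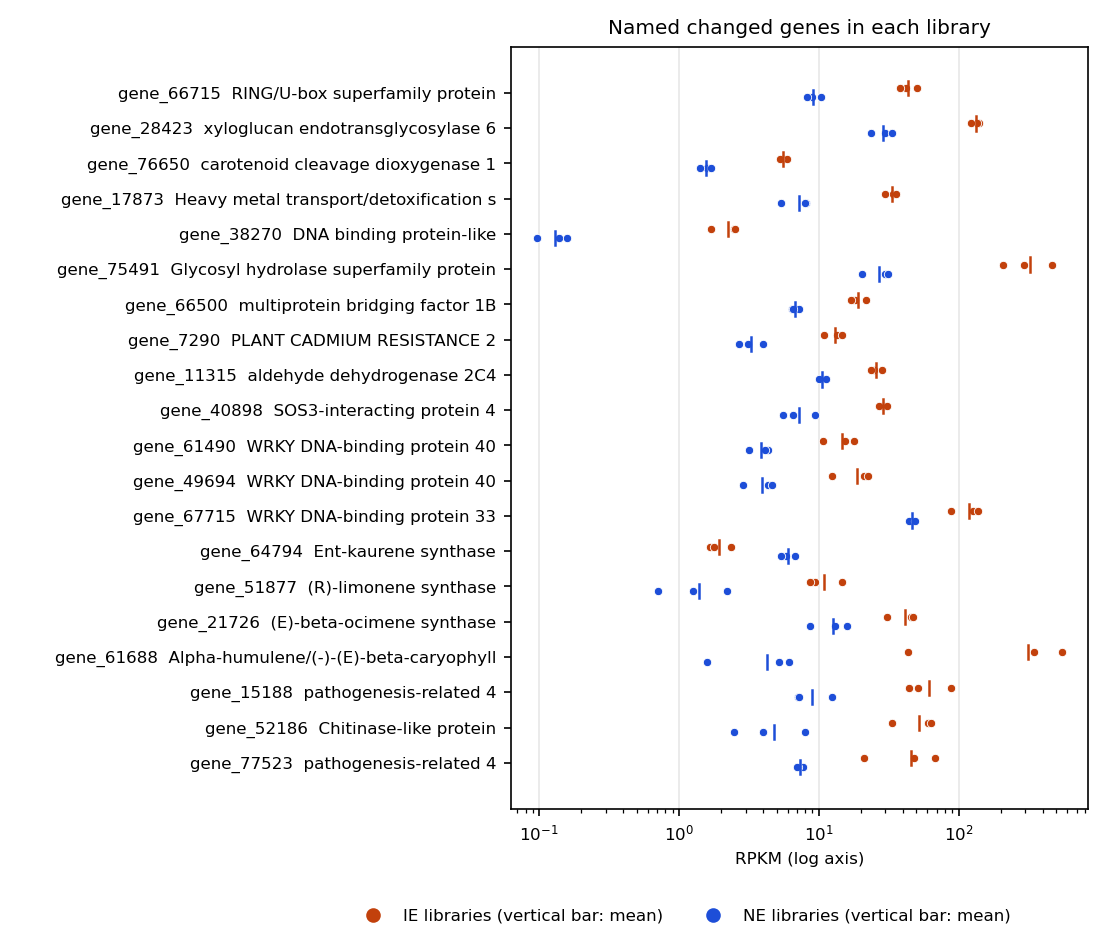
RPKM (log axis) of 20 named genes in each library, with IE libraries in orange and NE libraries in blue (1 dot per library, vertical bar at the mean of 3); names are those of the Arabidopsis or tomato match. In each gene the IE and NE dots do not overlap, and gene_61688 spreads from 43.5 to 546 RPKM among the IE libraries.

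Among terpenoid genes, 3 of 12 tested terpene synthases rose in IE, 1 fell and 8 did not pass. Adjusted over the list alone, 8 rose and 1 fell. The gene matching alpha-humulene/(E)-beta-caryophyllene synthase, gene_61688, was at 347, 43.5 and 546 RPKM in the 3 IE libraries and at 5.2, 6.12 and 1.58 in NE, a log2 fold change of 5.40 ± 0.94 (SE) with an adjusted p of 0.0465. The genes matching (E)-beta-ocimene synthase (gene_21726) and (R)-limonene synthase (gene_51877) rose to 41.1 ± 9.15 from 12.6 ± 3.68 RPKM and to 10.9 ± 3.26 from 1.4 ± 0.77 (SD, n = 3 each). The models of gene_61688 and gene_21726 span only positions 1 to 540 and 10 to 482 of their scaffolds. They may be partial genes, and a short span raises RPKM against that of other genes. The ent-kaurene synthase gene_64794, which acts early in gibberellin synthesis, fell from 5.99 ± 0.732 to 1.94 ± 0.377 RPKM (SD, n = 3 each). The list's median log2 fold change was 1.04, with a camera adjusted p of 0.00143 at the preset correlation and an adjusted p of 0.56 with an estimated correlation. The 3 that rose all match tomato chromosome 1 (Solyc01g101170, Solyc01g105900 and Solyc01g105860), on which IE libraries also lacked genes. The list's 5 members that match elsewhere did not pass the set test (camera adjusted p 0.503). They include gene_64794, which was itself called lower. Without NE library 2 the calls of gene_61688, gene_21726 and gene_64794 were lost (adjusted p 0.174, 0.162 and 0.0845), and that of gene_51877 was lost without NE library 3 (0.0983).

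The cytosolic route to isoprenoids, the mevalonate and sterol list, had 1 gene higher and 1 lower among 32 tested, and 14 higher and 2 lower when adjusted over the list alone. Its median log2 fold change was 0.27 (camera adjusted p 0.00143, and an adjusted p of 0.583 with an estimated correlation). The hydroxymethylglutaryl-CoA reductase gene_61050, the rate-limiting enzyme of this route, stood at 167 ± 102 RPKM in IE and 11.9 ± 4.51 in NE (SD, n = 3 each), a log2 fold change of 3.49 with an adjusted p of 0.0468. Its IE values were 241, 51.1 and 210 RPKM, and its call was lost without NE library 2 (adjusted p 0.179). The model of gene_61050 spans only positions 27 to 1144 of its scaffold and may be partial. The gene that fell was a squalene synthase (gene_46549), 1 of the 15 genes with almost no reads in IE. The plastid MEP pathway supplies the substrate of isoprene synthase. Of the 17 tested genes of the MEP list, 1 rose and none fell, and 14 had a negative log2 fold change. Among the 17, gene_54962, gene_50254 and gene_44484 have an Arabidopsis match annotated only as a transketolase family protein. Their place in this pathway is therefore uncertain, and the counts and the set test include them. Their log2 fold changes were -0.30, 0.23 and -0.08. The list did not pass the set test (camera adjusted p 0.0576), though it did, downwards, without IE library 2 (0.0289). Its 9 members that do not match tomato chromosome 1 did not pass the set test either (0.244). Adjusted over the list alone, 1 rose and 1 fell. The member that rose was an isopentenyl diphosphate isomerase (gene_51512, 6.19 ± 1.38 RPKM in IE and 2.05 in NE, adjusted p 0.0208), which lost its call without NE library 2 (adjusted p 0.131). None of the other members, which include the deoxyxylulose phosphate synthases and the hydroxymethylbutenyl diphosphate reductases, was called. By mean RPKM over all 6 libraries, the 3 highest members were a hydroxymethylbutenyl diphosphate reductase (HDR, gene_45999) at 38.6 ± 5.75 RPKM in IE and 62.2 ± 4.3 in NE, a deoxyxylulose phosphate synthase (gene_3193) at 26.8 ± 6.04 and 38.4 ± 4.69, and a hydroxymethylbutenyl diphosphate synthase (gene_34321) at 25.5 ± 4.41 and 36 ± 3.89 (SD, n = 3 each). Their adjusted p values were 0.0654, 0.182 and 0.158, so none passed. In NE alone a second HDR gene (gene_39674, 43.7 RPKM) was above gene_3193 and gene_34321.

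The WRKY, pathogenesis-related, peroxidase and P450 lists passed with a positive direction at the preset correlation, and none of them with an estimated correlation. Of 35 WRKY transcription factors, a family that controls defence genes, 3 rose and none fell, and 13 rose when adjusted over the list alone. The matches of WRKY40 (gene_49694 and gene_61490) and WRKY33 (gene_67715) rose by 1.97, 1.67 and 1.30 on the log2 scale, and gene_67715 was at 118 ± 26 RPKM in IE and 46.7 ± 2.47 in NE (SD, n = 3 each). The WRKY list had a median log2 fold change of 0.35 (camera adjusted p 8.17e-06, and an adjusted p of 0.56 with an estimated correlation). Of 28 salicylate and pathogenesis-related genes 3 rose and none fell (7 and 2 when adjusted over the list alone), and all 3 encode chitinase-like proteins: gene_52186 at 52.5 ± 16.8 RPKM in IE and 4.83 ± 2.88 in NE, and the pathogenesis-related 4 genes gene_15188 and gene_77523, both matching Solyc01g097270 on tomato chromosome 1, with log2 fold changes of 2.63 and 2.34. Of 38 class III peroxidases 3 rose and none fell (8 and 3 when adjusted over the list alone), among them gene_21017 with 228, 30.7 and 87.2 RPKM in the IE libraries and 5.88 ± 0.253 in NE (SD, n = 3), and gene_28326 with a log2 fold change of 2.64. Cytochrome P450 genes changed in both directions, 5 higher and 1 lower of 68 (14 and 4 when adjusted over the list alone). The median log2 fold changes of the pathogenesis-related, peroxidase and P450 lists were 0.38, 0.18 and 0.24, with camera adjusted p of 0.00374, 0.00611 and 0.00934 and, with an estimated correlation, adjusted p of 0.566, 0.56 and 0.56. The pathogenesis-related list did not pass without IE library 1 (camera adjusted p 0.0556), and its median was 0.66 without IE library 2. The peroxidase list did not pass without the genes matching tomato chromosome 1 (0.0843). The calls of the WRKY, chitinase and peroxidase genes named here were each lost without NE library 2, with adjusted p between 0.0931 and 0.195.

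Smaller shifts were found in 3 further lists that passed with a positive direction. Disease resistance proteins had 1 higher of 81 (median log2 fold change 0.10, camera adjusted p 0.0212), phenylpropanoid and lignin genes 0 of 46 (0.17, 0.0395) and NAC factors 0 of 34 (0.06, 0.0447). Their adjusted p with an estimated correlation were 0.566, 0.769 and 0.56, and their camera adjusted p rose to 0.195 without IE library 3, 0.337 without IE library 1 and 0.205 without IE library 1. Without the genes matching tomato chromosome 1 the phenylpropanoid and NAC lists did not pass either (0.0528 and 0.0843). The phenylpropanoid median was 0.32 without IE library 2, and the NAC median 0.01 with quantile normalization. Jasmonate pathway genes had 5 higher and none lower of 34, without passing as a list (camera adjusted p 0.0944). That list did pass without IE library 2 (0.00787) and without NE library 1 (0.0166). The members that rose included 2 matches of jasmonate ZIM domain 2 (gene_55427 and gene_58930, both with a log2 fold change of 1.56), which are repressors of jasmonate signalling, and both calls were lost without NE library 2 (adjusted p 0.127 and 0.18). Ethylene pathway genes had 2 higher and none lower of 51 (camera adjusted p 0.0517), and both encode aminocyclopropane carboxylate oxidase-like proteins (gene_32324 and gene_66963; adjusted p 0.143 and 0.131 without NE library 2). Adjusted over the list alone, 7 rose and 2 fell, and the ethylene list passed without IE library 2 (0.0119), NE library 1 (0.0266) or NE library 2 (0.0485) and with voom (0.0404).

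Ribosomal protein genes were shifted upwards by small amounts. Of 140 cytosolic ribosomal protein genes 117 had a positive log2 fold change, with a median of 0.17, and 1 passed on its own (gene_65946, ribosomal protein L44, 19.1 ± 1.42 RPKM in IE and 11 ± 1.68 in NE; SD, n = 3 each). Of 119 plastid ribosomal protein genes 3 rose, with a list median of 0.22. With quantile normalization the medians were 0.09 for the cytosolic and 0.14 for the plastid list. These 3 were the genes for S5 (gene_2722), S20 (gene_15268) and S10 (gene_34685), with log2 fold changes of 0.95, 0.90 and 0.66. Camera adjusted p were 1.28e-06 and 4.37e-06 for the cytosolic and plastid lists, and adjusted p with an estimated correlation were 0.566 for both. All 4 genes lost their calls without NE library 2 (adjusted p 0.201, 0.131, 0.159 and 0.214, in the order given).

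The 5 lists that passed with a negative direction covered photosystems, chlorophyll, senescence, drought and auxin. Photosystem and light-harvesting genes had a median log2 fold change of -0.19 and 67 of 96 members below 0, but no member passed (camera adjusted p 0.0129, and an adjusted p of 0.814 with an estimated correlation). Drought and osmotic stress proteins had 2 of 60 lower (median -0.21, camera adjusted p 0.000718, and 0.56 with an estimated correlation): an early-responsive to dehydration gene (gene_40154), which went from 8.62 ± 0.174 to 3.02 ± 1.2 RPKM (SD, n = 3 each), and a dehydration-responsive methyltransferase-like gene (gene_70497). Senescence genes (median -0.19, camera adjusted p 0.0134, and 0.56 with an estimated correlation) and chlorophyll synthesis genes (median -0.14, camera adjusted p 0.0395, and 0.814) each had 1 lower, of 39 and 41. Without IE library 2 these medians were -0.30 and -0.07. When adjusted over the list alone, 7 drought, 4 senescence and 2 chlorophyll genes were lower and none higher. The senescence and chlorophyll call over all genes was the same gene, gene_75179, annotated as a pheophorbide a oxygenase family protein and as chlorophyllide a oxygenase, which went from 26.9 RPKM in NE to 12.9 in IE. The calls of gene_40154 and gene_75179 were lost without NE library 2 (adjusted p 0.196 and 0.155) and that of gene_70497 without NE library 3 (0.189). The auxin list had 2 higher and 2 lower of 66, or 3 higher and 10 lower when adjusted over the list alone (median -0.18, camera adjusted p 0.0245, and 0.566 with an estimated correlation). The photosystem list did not pass without NE library 3 (camera adjusted p 0.649) or without IE library 1 (0.203). The senescence and chlorophyll lists did not pass without IE library 2 (0.273 and 0.504), nor the auxin list without IE library 3 (0.233).

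**Figure D2:**
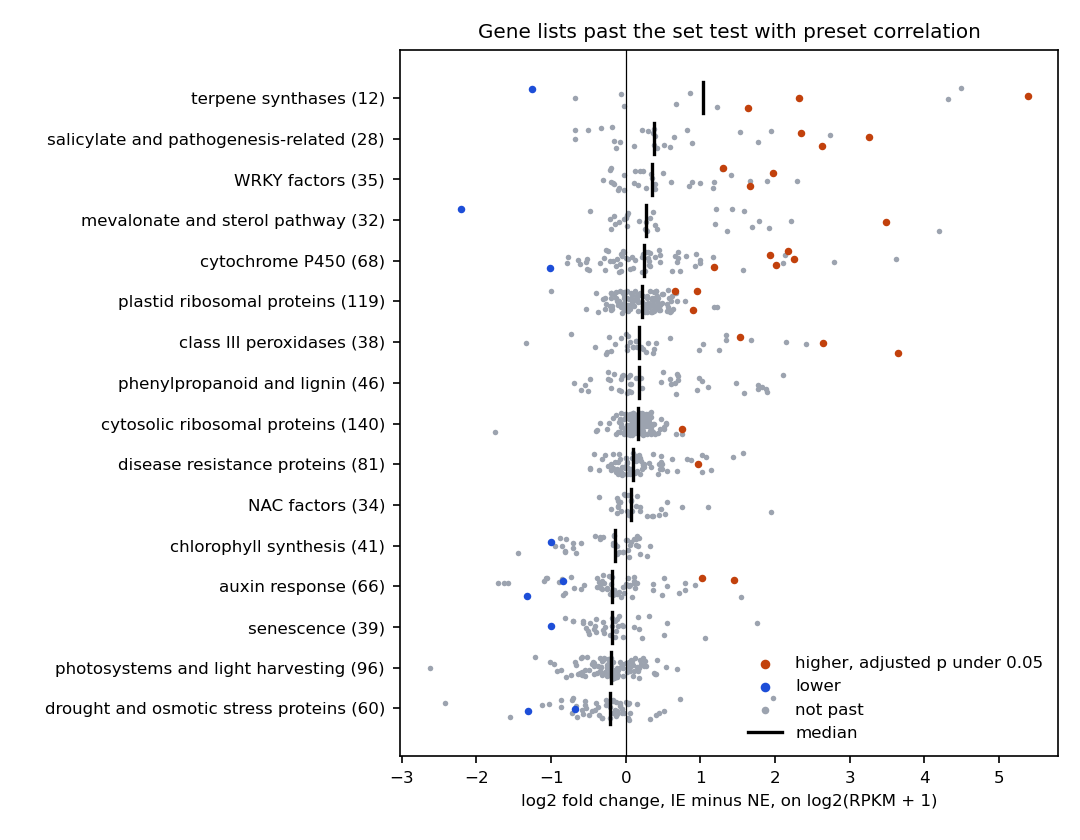
Log2 fold change (IE minus NE, on log2(RPKM + 1)) of each tested member of the 16 lists past the set test, with the number of members in brackets (dots, orange higher and blue lower at an adjusted p under 0.05, grey not past; black bar, median). Medians run from -0.21 for drought and osmotic stress proteins to 1.04 for terpene synthases.

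Other fixed lists held changed genes without passing the set test. Cell wall genes had 5 higher and 4 lower of 93 (17 and 6 when adjusted over the list alone), and their list passed without IE library 2 (camera adjusted p 0.00605). Those higher were 3 xyloglucan endotransglucosylases (gene_28423, gene_34153 and gene_56915) and 2 cellulose synthase-like E1 genes, and those lower included 2 pectate lyases (gene_72868 and gene_74106), enzymes that break down pectin, with log2 fold changes of -1.52 and -1.20. Calcium signalling and receptor kinase genes had 6 higher and 2 lower of 170 (8 and 3 by the same rule). Abscisic acid genes had 3 higher and none lower of 50, 2 of them receptors of the PYL family (gene_34387 and gene_50106), but 7 higher and 7 lower when adjusted over the list alone, and 32 of the 50 had a negative log2 fold change. Of the genes named here, gene_28423 and gene_72868 kept their calls in all 6 removals, and the others missed the threshold without NE library 2 (adjusted p 0.06 to 0.174). In all, 16 of the 45 lists passed at the preset correlation, 11 upwards and 5 downwards, and 8 others passed in at least 1 removal of a library. None passed with an estimated correlation (lowest adjusted p 0.56), and none by the directional fry test (lowest adjusted p 0.108), while 41 passed by the mixed fry test, which counts changes of either direction. Of those 8 others, the carotenoid metabolism list passed in the most removals, downwards in 4 of the 6. With all libraries its median log2 fold change was -0.24 (camera adjusted p 0.0576), with 1 higher and 1 lower of 38. In 10 lists, none of them among the 16, the median, mean and direction of the test differed in sign, the calcium list among them (median -0.02, mean 0.07).

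Markers of other tissues that a leaf sample can hold were followed with 5 lists, none of which passed the set test with all libraries. Markers of dividing cells had 2 lower of 81, the cyclins D1 (gene_19936) and D2 (gene_34877), which drive entry into the cell cycle, with log2 fold changes of -1.12 and -1.34 (camera adjusted p 0.0898). This list passed downwards without IE library 2 (0.0329). The calls of the 2 cyclins were lost without NE library 2 (adjusted p 0.131) and NE library 3 (0.067), respectively. The glandular trichome list had 1 higher of 18 (camera adjusted p 0.139), the trichome birefringence-like gene gene_71984 (adjusted p 0.196 without NE library 2). That gene is of a family known for acetylating cell wall polymers, so its call says little about glandular trichomes. Vascular (31 genes), flower and pollen (29) and root (6) markers had none past. The libraries of the lines were not equally alike. Correlations across genes of log2(RPKM + 1), in which genes are not independent replicates, were 0.975 to 0.978 between NE libraries, 0.905 to 0.959 between IE libraries and 0.882 to 0.919 between the lines. The first principal component, with 51.9% of the variance, parted the lines, and the second, with 27.7%, set IE library 2 (-41.2) apart from IE libraries 1 and 3 (9.62 and 23.4).

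All 10 genes with the smallest p among those lower in IE belonged to a set of 15 that had almost no reads in any IE library, defined after the values were seen as under 2% of the NE mean in each. The most abundant was a beta-galactosidase (gene_44872, scaffold Ntab-TN90_AYMY-SS2099), at 137 ± 37.5 RPKM in NE and 0.0624 ± 0.0128 in IE (SD, n = 3 each). It had 35 reads in the 3 IE libraries together and at least 18129 in each NE library, a level 2174-fold lower (95% exact Poisson interval 1563 to 3122, counting error only). The others by this rule were a SEC14-like lipid transfer protein (gene_37125), a vacuolar proton pump subunit a (gene_57550), a transmembrane receptor kinase (gene_44873), a chloroplast-splicing type CRM domain protein (gene_2233), a pyridoxal-dependent decarboxylase (gene_37124), an AAA-type ATPase (gene_37109), an SH3 domain protein (gene_46551), the squalene synthase gene_46549 and a RING/U-box protein (gene_37119). Their NE means ran from 3.05 to 15.4 RPKM, and each had at most 10 reads in the IE libraries together. For gene_46551, with 0 reads in IE, the level was at least 559-fold lower, against a floor of 3 reads over the group. The squalene synthase had 2 reads in IE and at least 836 in each NE library, a ratio of 1477 (95% exact Poisson interval 409 to 12200, given as counting error only). All 10 were called in each of the 6 removals, with adjusted p of at most 0.0107. The 15 genes lie on 5 scaffolds of the tobacco assembly, and their best tomato matches all lie on chromosome 1, between Solyc01g108840 and Solyc01g110300.

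Single IE libraries lacked further genes. Under 2% of the NE mean were 15 genes in IE library 1, 70 in IE library 2 and 44 in IE library 3, against 1 gene in each NE library when set against the other NE libraries. The NE counts cannot include a gene missing from all NE libraries, so the 15 genes missing from every IE library have no counterpart in them. The proteinase inhibitor gene_54534, for instance, was at 0.222, 0 and 0.0872 RPKM in NE and at a mean of 19.9 in IE. IE library 2 alone lacked 48 genes, 45 of them with a tomato match on chromosome 1, and IE library 3 alone lacked 22, of which 19 match tomato chromosome 5. The second HDR gene (gene_39674, named after its values were seen) was among those missing from IE library 2. Its tomato match, Solyc01g109300, is also that of gene_45999. The level of gene_39674 was 11.2, 0.0269 and 15.6 RPKM in the IE libraries and 43.7 ± 3.88 in NE (SD, n = 3), with an adjusted p of 0.176. Without the 88 tested genes that were near-absent in any IE library, 251 genes changed.

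**Figure D3:**
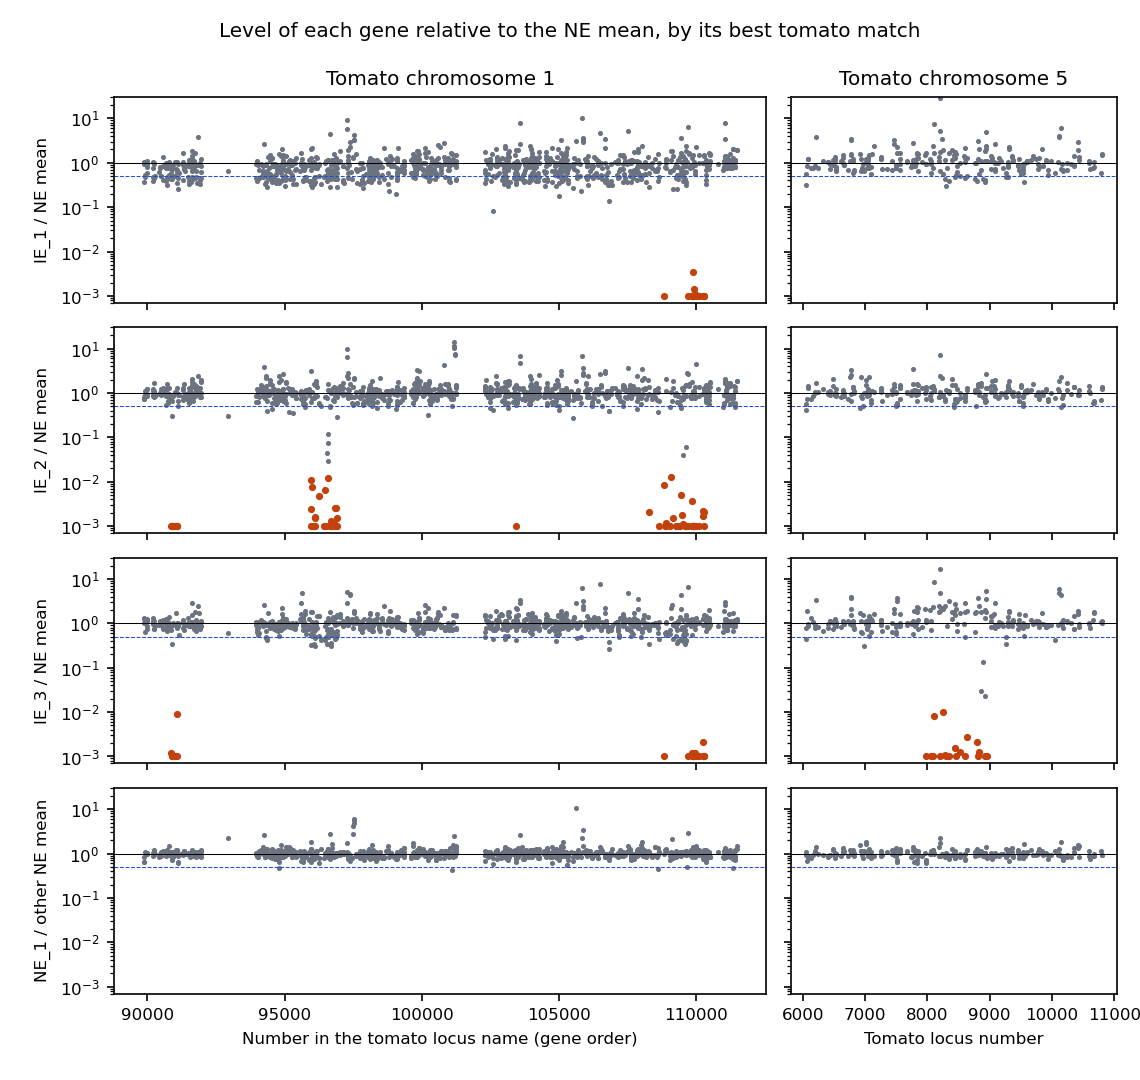
Level of each gene relative to the NE mean (log axis) in IE libraries 1, 2 and 3 and in NE library 1 (relative to the other NE libraries), by the number in the name of its best match on tomato chromosomes 1 and 5, which gives gene order and not distance. Orange dots are genes under 2% of the NE mean, values under 0.001 are drawn at 0.001, and the lines mark 1 (solid) and 0.5 (dashed); 15 genes are orange in all 3 IE libraries.

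In the authors' deposited table, which gives its own fold changes and p-values, 224 genes had an adjusted p under 0.05, 150 of them higher and 74 lower in IE, and 181 changed at least 2-fold (122 higher and 59 lower). Of these, 220 were among the genes tested here and 205 were called by both, all in the same direction. Both come from the same 6 libraries, so the overlap is no independent check. Of the 40 genes of the naming rule that were called here, 32 were called in the authors' deposited table and 8 were not. These 8 were gene_61688, the caryophyllene synthase match (log2 fold change 5.71, adjusted p 0.153), the limonene synthase match gene_51877 (0.061), the peroxidases gene_21017 (0.0829) and gene_77868 (0.0679), the drought list's gene_40154 (0.0672) and gene_70497 (0.08), and the ribosomal protein genes gene_65946 (0.0572) and gene_34685 (0.0685). Of the 3 terpene synthases raised here, gene_21726 alone was called in the authors' deposited table (0.0449). The RING/U-box gene gene_66715 and the beta-galactosidase gene_44872 were called in the authors' deposited table as well (2.23 with 0.00341, and -11.01 with 0.00304).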

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

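The tests with recovered reads, quality weights, other scalings, other near-absence thresholds or left-out genes were chosen after the data were seen, and the other alternatives before. No paired analysis was possible because the column numbers 1 to 3 carry no sample of their own and differ from the replicate numbers in the titles. The planned normalizations and tests for counts, and the stricter filter on counts, were tied to a count table and were not run. Of the methods for counts, only voom was run on the recovered reads. The fold changes of the 43 genes of the naming rule kept their sign in each alternative that tested them, and the other named genes were not followed through all alternatives. However, the balance of higher and lower calls did change. The 266 changed genes became 1090 with sample quality weights, and between 29 and 1095 with 1 library left out. The 173 genes changed at least 2-fold became 452 with quality weights and between 29 and 486 with 1 library left out. Fewer libraries may account for part of the losses. With as many libraries left, however, the count rose to 1095 without IE library 2 and to 465 without IE library 3. The quality weights (0.291 for IE library 2, 1.87 for NE libraries 1 and 3) and the removal of IE library 2 both lessen that library's part in the spread. No cause of these shifts was tested. The 16 gene lists became 0 with an estimated correlation, which by construction widens the test for lists whose members vary together, and between 11 and 21 with 1 library left out. All 16 kept their direction in the 6 removals and 8 also their call, while 8 other lists passed in at least 1 removal. The other alternatives gave between 220 and 333 changed genes, between 144 and 232 changed at least 2-fold, and between 12 and 22 lists. The 12 came from leaving out the genes that match tomato chromosome 1, which cut the upward lists from 11 to 7 (terpene synthase, peroxidase, phenylpropanoid and NAC lists lost) and left the 5 downward ones. Of the calls, 68.8% were higher in IE; this was 61.3% with quantile normalization, 53.7% without IE library 1, and 50%, 24.1% and 45.2% without NE library 1, 2 and 3. Without the 15 genes missing from IE, called in each removal, the share was 72.9%, and 69.2% without IE library 1 and 72.7%, 50% and 87.5% without NE library 1, 2 and 3. Of 40 named calls, 15 held in every alternative that tested them and 25 were lost in at least 1. The near-absent genes numbered 15 at thresholds of 1%, 5% and 10% of the NE mean as well. With 10 splits of the 6 libraries into 3 and 3, the share with as large a result is never under 0.1. The real split gave 266 changed genes, 173 at least 2-fold and 16 lists, the highest other split 0, 0 and 18, and as many or more were found in 1, 1 and 3 of the 10 splits, the real one included, so the splits are too few to decide. Depth limits little at these levels: the listed genes have at least 10 CPM in 3 libraries.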

Other observations

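The gene groups and the tests of hypotheses in this part were chosen after the values were seen, except the tests of a replacement by the partner copy and of reads assigned to it for the genes missing from all 3 IE libraries, taken as a set, whose tests were set before their results. Of 6 further groups looked at by description, proteinase inhibitors, which block the gut enzymes of plant-eating insects, had 4 higher and none lower in IE of 9 tested. The chymotrypsin inhibitor genes gene_67143 and gene_68653 were at 383 ± 239 and 290 ± 188 RPKM in IE and at 23.5 ± 11.5 and 12.2 ± 5.32 in NE (SD, n = 3 each), and the proteinase inhibitor II genes gene_54534 and gene_73393 had log2 fold changes of 3.94 and 2.28. Of 12 asparagine and glutamine synthetases, 2 asparagine synthetases rose (gene_65233, 91.4 ± 41.5 RPKM in IE and 10.5 ± 5.6 in NE, and gene_73145) and 1 glutamine synthetase fell (gene_12608, 0.441 and 3.35 RPKM). Of 12 amine oxidases 2 copper amine oxidases fell, gene_57660 from 43.6 ± 11 to 7.65 ± 2.64 RPKM and gene_76230 from 11.1 to 3.53. Aquaporins had 1 higher of 21, chitinases and glucanases 4 higher of 20 and cyclins 2 lower of 14. The chitinase, glucanase and cyclin calls are genes already named above, so they add no new calls. The calls of the proteinase inhibitor, synthetase and amine oxidase genes named here were each lost in at least 2 removals of a library, with adjusted p of at most 0.186, and those of gene_54534 and gene_73393 also with voom (0.138 and 0.0618).

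Tobacco carries the gene sets of 2 ancestors, and pairs of gene models with the same tomato match mostly moved together. Among 3250 tested pairs without near-absent genes, the partner of a changed gene had the same direction in 111 of 118 cases (94.1%), against 48.5% with random partners and at most 63.6% in 10000 draws. In 36 cases the partner was itself changed. Such a pair enters once from each of its genes, so the cases are not all independent, while the random draws treated them as if they were. Reads shared between near-identical copies would also give this, and that was not tested.

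Of the 15 genes missing from all 3 IE libraries, 14 share a scaffold with another, against at most 4 in 10000 random draws of listed genes (permutation p 0.0001, the smallest these draws can give). Their 5 scaffolds hold 24 listed genes, and the other 9 were not near-absent in any IE library. By tomato match, 14 of the 15 are among 35 listed genes from Solyc01g109730 to Solyc01g110300, of which 21 were not near-absent. The match of the remaining one is Solyc01g108840; of the 45 listed genes after it and before Solyc01g109730 none was missing from all 3, 16 were missing from IE library 2 alone and 29 were not near-absent. Depth was enough to detect these genes, since the NE level predicts a median of 672 reads per gene and IE library and at least 387. The filter of at least 10 CPM in 3 libraries ensured this beforehand, so it is not a check that could have failed. For the set as a whole, assignment of their reads to the partner gene model is argued against: in 9 pairs the summed level of both copies was 0.56 of that in NE in the median (95% bootstrap interval 0.456 to 0.724). The partners stood at 1.06 times their NE level (0.764 to 1.41), below the 1.5 that a replacement by the other subgenome's copy was taken to need, although the interval does not fall under the lower bound set beforehand for ruling it out; the partner of the beta-galactosidase alone was at 2.68. For that pair the summed level was 1.22 of NE, so assignment of its reads to the partner, or replacement by it, stays open for this gene. A candidate explanation is that the IE line lost these genes in 1 subgenome, and whether the genes are deleted or silenced, and whether isoprene synthase or the transformation has a part in it, was not tested.

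For the 48 genes missing from IE library 2 alone, most of them in 2 runs on tomato chromosome 1, the other IE libraries held intermediate levels. Their median was 0.492 of the NE level in IE library 1 (95% bootstrap interval 0.449 to 0.527) and 0.524 in IE library 3 (0.45 to 0.554). Each interval covers only the spread between genes within 1 library, with neighbouring genes treated as independent. Partner gene models in 32 pairs were at 1.07, 1.02 and 1.04 in IE libraries 1, 2 and 3. For these pairs the value of 1.02 (0.837 to 1.16) argues against replacement by the partner copy in IE library 2. These levels are consistent with a loss that differs between libraries of the IE line, with 1 of 2 allelic copies missing in IE libraries 1 and 3 and both in library 2. In IE library 1 the lower levels also reach beyond these runs: of 1244 genes matching tomato chromosome 1 from locus number 80000 on, 28.5% lay between 0.3 and 0.65 of the NE mean, against 8.95% of genes elsewhere and at most 17.2% in a block of at least 50 genes on other chromosomes. The same share was 10.5% in IE library 2 against 10.7% elsewhere, 4.9% in IE library 3 against 5.03%, and 1.53% to 2.25% in NE libraries. The 3 raised terpene synthases and the 2 raised pathogenesis-related 4 genes also match this part of chromosome 1 (Solyc01g097270 to Solyc01g105900), and whether their rise has to do with the losses was not tested. Higher calls as a whole were not more frequent on chromosome 1: 20 of the 183 match it, as do 1740 of the 13152 tested genes. A further 7 genes (Solyc01g090850 to Solyc01g091080) were missing from IE libraries 2 and 3 and at 0.873 of NE in library 1.

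The 19 genes on tomato chromosome 5 (Solyc05g007980 to Solyc05g008960) that were missing from IE library 3 alone behaved otherwise. They stood at 0.534 of NE in IE library 1 (0.456 to 0.667) and near their NE level in IE library 2 (0.902 to 1.17). Their partners, in 14 pairs, stood at 2.24 times the NE level in IE library 3 (95% bootstrap interval 1.95 to 2.69), at 1.75 in IE library 1 (1.31 to 2.05) and at 0.97 in IE library 2 (0.817 to 1.18). This may be an exchange between the subgenomes in which the partner copy took the place of the missing one. The sum of both copies was 1.11 of NE in IE library 3 (0.958 to 1.68), which assignment of the reads to the partner gene model would also give, and the 2 cannot be told apart without sequences of the reads. Near-absent genes so differed between libraries of 1 line.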
